A study of Solanum tuberosum with 30 samples.

How the data were processed

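The deposited values are log2 ratios of the 2 channels of each array, 1 value per spot and array, which the authors had normalised by a method not given in the sources used here. The submitters' notes name limma without a version or a role, and scanner, background correction and spot filter are not given in the sources used here. Every deposited value was the log2 of a ratio in steps of 0.01, once negative values were taken as stored 0.001 higher, which fixes the base. Array medians ran from −0.043 to 0.014, and the spread of an array, as a scaled median absolute deviation, from 0.285 to 0.727. Of 32448 spots, 10610 had no value on any array and 6831 had one on all 30. An array had a value on 11947 to 20316 spots. The layout of duplicates was inferred from the table: all 905 annotated clones sat on 2 spots at a fixed offset, and the same offset paired the other spots into 15360 clones. The 2 spots correlated at r = 0.935 over all arrays, from 0.798 to 0.968 on single arrays, and were averaged, which left 11074 clones with a value.

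Per the labels, drought extracts carried Cy3 and control extracts Cy5 on 29 arrays, and the dyes were exchanged on 1. Dye is thus confounded with treatment on those 29 arrays. A dye effect of a clone cannot be told apart there from a drought response. Ratios were read as Cy5 over Cy3, so that the drought-control difference is the deposited value with its sign turned. The sources used here do not state this direction. The exchanged array correlated at r = 0.780 across clones with its partner of the same 2 extracts. Either the submitters had already turned it or dye effects outweighed the treatment. A dye effect that large, if all arrays shared it, would make arrays of different sets correlate above 0. Their r had a median of 0.0117 over 368 pairs, with 35 below −0.3, which argues against a shared effect of that size. A dye effect of this pair alone cannot be told apart from values already turned. The array was left as deposited and read like the others, and the pair was averaged. On each of the 6 complete sets the labelled pairing of plants closed best (unexplained share 0.0736 to 0.194, against at least 0.411 with any sign turned).

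The 32 extracts were 16 of control and 16 of drought plants, and the extract of a plant, not the array, was taken as the replicate. The labels give 2 control plants per line and cycle, so leaf and tuber extracts may come from the same plants, and they were treated as independent. With R 4.3.3 and limma 3.58.1 each clone was fitted by generalised least squares with 1 coefficient per set of line, tissue and cycle, over all arrays together. Arrays that share 1 plant carried a consensus correlation of 0.414, estimated from 8849 clones. Sums of squares pooled over the same clones put 84.6% of the variance of a ratio on its 2 plants. Variances were moderated by limma (prior degrees of freedom 3.52, prior SD 0.433), with Benjamini-Hochberg adjustment over all clones tested. A clone was called changed at an adjusted p under 0.05, two-sided, or by an F-test for the 3 lines. Clones needed a value in every set of a contrast. Standard errors are those of this fit. The comparisons, their alternatives, the gene lists and the rule for named genes were written before the data were examined. The responses of single sets were added later, from the same fit, and the assignment of product names to gene symbols was made from the symbols alone, before any fit.

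The rule for named genes took, in each of the 4 mean responses, up to 10 genes with the largest rise and 10 with the largest fall among clones past the threshold with the same sign in every set and a named product, 1 clone per gene, the one with the smallest p. For the other comparisons it took 5 each way, or the 10 with the largest F, without the sign criterion, and from each list up to 4 members past the threshold. Where none passed, the 3 with the smallest p are given as values. Of 24 fixed gene lists, 22 had a measured clone and 15 had the 3 clones needed for a test. Lists were tested with cameraPR on the moderated statistics with a preset correlation of 0.01, a change from the planned camera on whitened values, which needs clones without missing values. Camera with an estimated correlation and fry were run on whitened values of clones complete on the arrays of a contrast. Of 163 list tests, 25 passed with the preset correlation and fry called 1. With an estimated correlation 0 of the 25 passed, and for 1 of them it could not be estimated. The preset correlation counts repeat clones of a gene as nearly independent. The test with an estimated one took its residual degrees of freedom from the arrays of the contrast alone, at most 4 for a single set. Its power was low there, so a list lost with it is not shown to be unchanged.

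Alternatives treated arrays as independent, used only arrays that share no plant, fitted tissues apart, centred or scaled arrays, kept only complete clones, weighted arrays, used robust moderation, added a fold threshold, left out each plant in turn, treated the exchanged array and the A array of the second cycle differently, and blocked on plant number. Alternatives chosen after the data were seen tested each spot alone, turned the B tuber set of the first cycle, or left out 1 C array.

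The fit was tested on simulated data with the same arrays, missing values and correlation. The simulated values followed the fitted model, with normal effects independent between clones and 1 spread per clone over all sets. The real arrays had quality weights from 0.283 to 1.98. The shares below therefore do not cover unequal spread of arrays or sets, or clones that vary together. For the mean tuber response to the first drought it recovered 74.6%, 91.0% and 100% of clones simulated at log2 1, 2 and 3, with 3.80% of calls false. For A tubers alone it recovered 35.8%, 80.6% and 93.9%, with 4.11% false, and with arrays taken as independent 72.7% of calls were false. The changed clones for A were drawn from the 7591 tested in the tubers of all 3 lines, not from the 10433 tested in A. The recovery in A therefore does not cover clones without a value in B or C. Without any simulated change, 4 simulations gave at most 2 calls in a contrast. Figures and summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Clones without a gene, or with several, were tested but not named.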

Results

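RNA from leaves and tubers of 3 Andean potato lines, called A, B and C here, was compared between plants kept without water and watered control plants on 30 two-colour cDNA arrays. The lines belong to Solanum tuberosum var andigena, and the plants were raised from seed in a greenhouse. Water was withheld while photosynthesis was monitored, the plants were watered again, and tissue was taken after the first or after the second such cycle. Each array paired the extract of 1 drought plant with the extract of 1 control plant. The arrays formed 9 sets by line, tissue and cycle, with 11 arrays of leaf and 19 of tuber, and 17 of the first cycle and 13 of the second. A leaf, A tuber and B tuber in the first cycle, and B leaf, B tuber and C tuber in the second, each held 4 arrays, every pairing of 2 drought with 2 control plants. The B leaf set of the first cycle held 3 arrays of 1 drought plant and 2 control plants, with 1 pairing repeated with the dyes exchanged. C tubers of the first cycle held 2 arrays of 2 drought plants against the same control plant, and A tubers of the second cycle held 1 array. An array gave a value for 6872 to 10646 cDNA clones, each spotted in duplicate, out of 11074 clones with a value on any array. The number of plants limited the precision, and depth has no meaning for such ratios. A gene could be put to 905 clones, and a product to 284 clones of 153 genes, so most changed clones below stay without a name. The gene table of the assembly SolTub_3.0 placed the named genes on scaffolds outside any chromosome, and their positions are left out.

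In tubers of line A after the first drought, transcripts of the photosynthetic apparatus fell. The comparison asked which transcripts differed between 2 drought and 2 control plants, over 4 arrays. MSP-II (LOC102577592), the PsbO protein of the oxygen-evolving complex, fell by 3.62 on the log2 scale (SE 0.806, adjusted p = 0.0130). All higher and lower statements here and below read the deposited ratio as control over drought. This direction was assumed and not tested. The statements would swap if the ratio ran the other way, with sizes and p values unchanged. A dye effect of a clone would also be read as a drought response. The chlorophyll-binding antenna protein cab1 (LOC102596966) had a log2 change of −2.45 ± 0.521 (SE, adjusted p = 0.0101) in its clone with the smallest p and of −3.34 in another (adjusted p = 0.0413), the photosystem II protein PSBR −2.41 ± 0.486 (adjusted p = 0.0104) and the oxygen-evolving protein OEE2 −2.94 ± 0.808 (adjusted p = 0.0428). SHMT, serine hydroxymethyltransferase of the photorespiratory glycine-serine conversion, fell by 3.78 (SE 0.623, adjusted p = 0.00252), and cTPT, a triose phosphate translocator, by 1.47 (SE 0.428, adjusted p = 0.0471). These 6 genes were lower in drought on all 4 arrays. Of the list of photosystem and light-harvesting genes, all 14 measured clones had a value below 0, with a median of −2.76. They were repeat clones of MSP-II, cab1, PSBR and OEE2 alone, so here and below they do not count as independent genes. Of these, 8 passed the threshold over all clones and 13 adjusted over the list alone. The list as a whole was lower than other clones with a preset correlation (adjusted p = 7.00e-12), which was lost at adjusted p = 0.394 with an estimated correlation. MSP-II, OEE2 and cTPT lost the threshold with tubers fitted apart from leaves, cab1, PSBR and cTPT with only arrays that share no plant. The list had also been set down as a marker of green tissue in tubers, together with the Calvin cycle list, whose 2 clones of the epimerase PPE were below 0 (median −0.82), past the threshold adjusted over the list alone and not over all clones.

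Genes outside photosynthesis moved both ways in the same A tubers. StWIPK (LOC102585585), a MAP kinase of the wound-induced type, had a log2 change of −2.11 ± 0.302 (adjusted p = 0.00119), and agpS3, a small subunit of the starch enzyme ADP-glucose pyrophosphorylase, of −1.49 ± 0.253 (adjusted p = 0.00347, a value on 2 of the 4 arrays, which share drought plant 1, so that the drought side is 1 plant). The ATP sulfurylase met3-2, of sulphate assimilation, and CCoAMT, a methyltransferase of lignin synthesis, changed by −2.15 ± 0.463 (adjusted p = 0.0103) and −1.50 ± 0.371 (adjusted p = 0.0213). A chitinase (LOC102590998) of the list of pathogenesis-related proteins changed by −1.20 ± 0.329 (adjusted p = 0.0422). It was named from that list only and was not followed through the alternatives below. The genes that rose, on all 4 arrays each, were the co-chaperone dnaJ (1.48 ± 0.319, adjusted p = 0.0105, and 1.83 in another clone, adjusted p = 0.0314), the auxin-response repressor IAA2 (1.44 ± 0.403, adjusted p = 0.0413), the protein phosphatase StP2C (1.39 ± 0.362, adjusted p = 0.0319) and the urease accessory gene ureG (0.92 ± 0.264, adjusted p = 0.0442). Of the 5 clones in the heat shock and chaperone list, all of dnaJ, 4 rose and the list median was 1.48 (adjusted p = 4.88e-05, and adjusted p = 0.394 with an estimated correlation). The polyamine list holds repeat clones of AdoMetDC and 1 clone of the spermidine synthase SpdSy. Of its 9 measured clones, 7 were below 0, 1 of AdoMetDC fell over all clones and 4 adjusted over the list alone (median −0.67, adjusted p = 0.00226, and adjusted p = 0.394 with an estimated correlation). In all, limma called 525 of 10433 clones, 273 higher and 252 lower in drought, of which 25 clones of 18 genes had a product. Drought plant 1 weighed most on this result, since 11 clones were called without it, against 108 without control plant 1, 150 without control plant 2 and 555 without drought plant 2. Without drought plant 1 only StWIPK of 13 named genes passed (adjusted p = 0.0146, the others 0.134 to 0.552, agpS3 without a value), without drought plant 2, with which agpS3 has no value, all 13 but CCoAMT (0.0540), StP2C (0.0793) and cTPT (0.0915), without control plant 1 StWIPK, SHMT and agpS3, without control plant 2 StWIPK, agpS3 and dnaJ, and with every array scaled to 1 spread only StWIPK and SHMT, among 28 clones. With tubers fitted apart from leaves 234 clones passed, without MSP-II (adjusted p = 0.0668), OEE2 (0.149), cTPT (0.106), StP2C (0.0802), ureG (0.0658) and CCoAMT (0.0606), and with only arrays that share no plant 41 passed, without cab1 (0.0608), PSBR (0.0542), cTPT (0.266), dnaJ (0.196), IAA2 (0.116), StP2C (0.153), ureG (0.154), met3-2 (0.156), CCoAMT (0.141) and agpS3 (0.138). cTPT was also lost with centred arrays (0.0507) and with complete clones only (0.0517).

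Tubers of B showed no such fall after the same first drought. The 14 photosystem clones were all above 0 in the fit of B, with a median of 0.74 (adjusted p = 0.0256, and adjusted p = 0.770 with an estimated correlation), while 0 of them passed the threshold. The 5 dnaJ clones were all below 0 in B, with a median of −0.65 (adjusted p = 0.0256, and adjusted p = 0.591 with an estimated correlation). The genes of B tubers with the smallest p were StP2C (−1.31, adjusted p = 0.318), AAC, the mitochondrial ADP/ATP carrier (0.72), and LPD2, a lipoamide dehydrogenase (0.80), which passed only with array quality weights (adjusted p = 0.0181, 0.0386 and 0.0288) or with arrays taken as independent. Array medians of the photosystem list were 1.82 and 1.96 against control plant 1, but −0.89 and −0.24 against control plant 2. In B, 0 of 10784 clones passed by limma, with 899 at an unadjusted p under 0.05, where chance alone would give about 1 in 20. With array quality weights the count was 311, without control plant 1 it was 6 and the photosystem median −0.89, and without drought plant 2 the count was 2.

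Tubers of C, measured on 2 arrays that share their control plant, gave low photosystem values like those of A. The list median was −3.14, with 13 of 14 clones below 0 and 10 past the threshold adjusted over the list alone, but 0 over all clones (adjusted p = 7.96e-15, and adjusted p = 0.919 with an estimated correlation). cab1 was at −3.10 ± 0.648 (adjusted p = 0.0929, and 0.0286 with array quality weights), cTPT at −1.99 and CYP74D2, a divinyl ether synthase of oxylipin metabolism, at 2.50 (adjusted p = 0.278). Lea, a late embryogenesis abundant protein and the only measured clone of the dehydrin list, was at 1.63 in C and 1.12 in A, each at an unadjusted p under 0.05 but not past the threshold over all clones. By limma 5 of 7665 clones passed in C, and they are named by spot number after their values were seen. Spots 161634 (5.64 ± 0.520, adjusted p = 9.24e-05), 158624 (2.74), 145150 (2.12) and 142031 (1.60) were higher but had a value on 1 of the 2 arrays, so each compares 1 drought with 1 control plant and takes its spread wholly from other sets. Spot 148106 was lower on both (−3.36 ± 0.606, adjusted p = 0.0335). None of these 5 clones has a gene name. The value of spot 161634 is the lowest deposited one of either C array, −5.643, with its sign turned. It lies near the floor of ratios in steps of 0.01, which also holds for its part in the mean response below.

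Averaged over the lines, the first drought gave low values of photosystem transcripts in tubers, and 13 of the 14 clones were below 0. Their median was −1.64, with 11 past the threshold adjusted over the list alone and 0 over all clones (adjusted p = 5.01e-14, and adjusted p = 0.266 with an estimated correlation). The 3 named genes with the smallest p were cab1 (−1.61 ± 0.327, adjusted p = 0.0637), cTPT (−1.17 ± 0.269, adjusted p = 0.0702) and SHMT (−1.71 ± 0.391, adjusted p = 0.0702). The dnaJ clones had a median of 0.44, all 5 above 0 (adjusted p = 0.0220, and adjusted p = 0.424 with an estimated correlation). By limma 3 of 7591 clones passed, without a gene name and chosen after their values were seen. They were spots 161634 (1.80 ± 0.242, adjusted p = 0.0126), which rests on a single C array, 148106 (−1.73 ± 0.306) and 151225 (−1.73 ± 0.320). The count was 0 without A drought plant 1, B control plant 2, B drought plant 1 or C drought plant 2, 6 without A control plant 1 or B drought plant 2, 9 without C drought plant 1, 58 without B control plant 1 and 101 without A drought plant 2. In the last-named fit cab1 (adjusted p = 0.0230), cTPT (0.0426) and SHMT (0.00383) passed, as they did without B control plant 1 (0.0121, 0.0214 and 0.0214), while cab1 also passed without C drought plant 1 (0.0439) and SHMT without A control plant 1 (0.0184). All 3 also passed with array quality weights (0.0125, 0.0141 and 0.0299), with arrays taken as independent, and with the B tuber set turned (0.00130, 0.0174 and 0.00130), chosen after the data were seen.

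**Figure D1:**
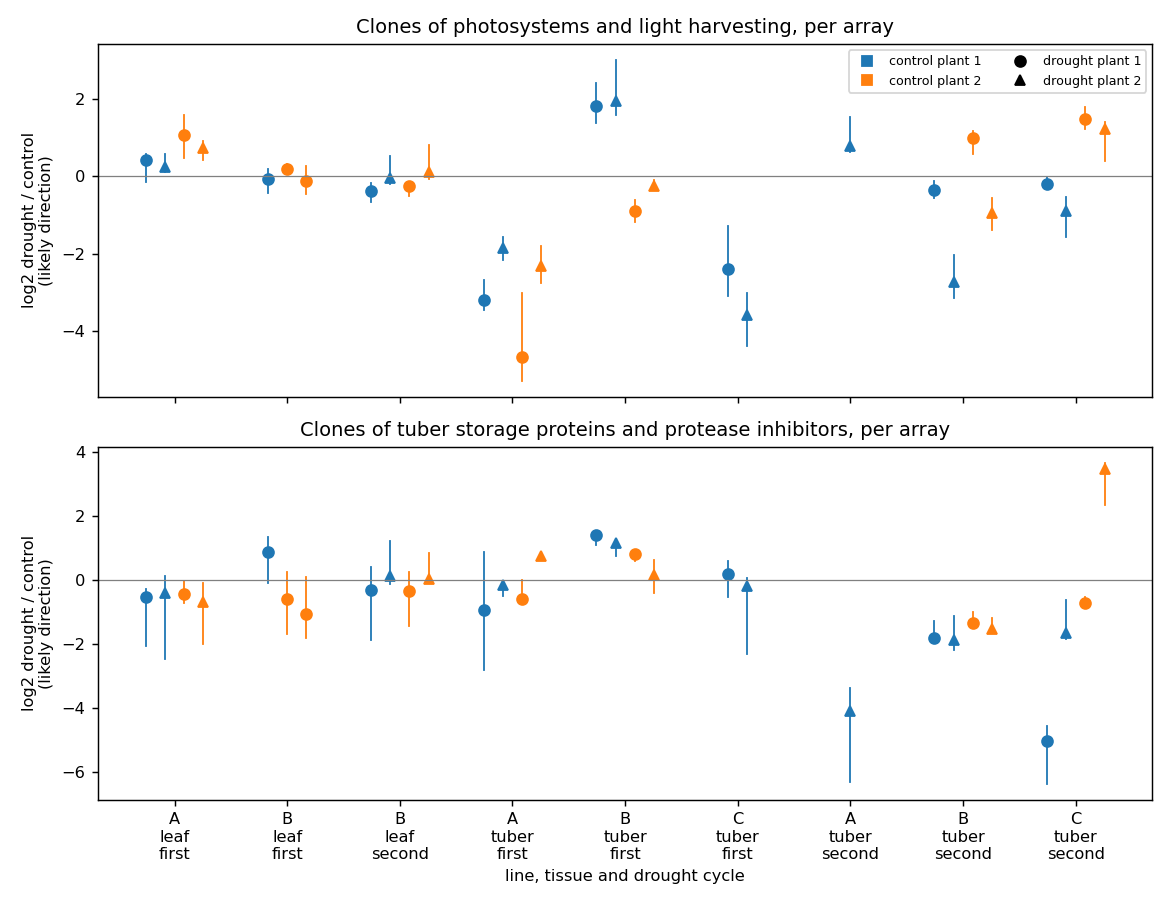
Median drought-control log2 ratio (y axis, points, with quartiles as bars) of the photosystem list and the storage protein list on each array, by set (x axis), with colour for the control plant and shape for the drought plant. The photosystem medians of A tubers in the first cycle ran from −4.66 to −1.86, while those of B tubers ran from −0.89 to 1.96.

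The lines differed in their tuber response to the first drought, and the difference was tested directly. SHMT differed most among the named genes (F = 16.7, adjusted p = 0.0117), at −3.78 in A, 1.17 in B and −2.53 in C. cab1 (F = 13.8, adjusted p = 0.0188) was at −2.45, 0.72 and −3.10 in the same order, and StWIPK (F = 15.6, adjusted p = 0.0145) at −2.11, −0.01 and 0.23. The C value of StWIPK rests on 1 array, with drought plant 1 against the control plant. StP2C (F = 14.7, adjusted p = 0.0188) and dnaJ (F = 11.8, adjusted p = 0.0258) were highest in A and lowest in B, at 1.39 and 1.48 in A, −1.31 and −0.71 in B, and 0.67 and 0.46 in C. The remaining named genes were LPD2 (F = 14.3, adjusted p = 0.0151), the calcium-dependent protein kinase CDPK2 (F = 9.45, adjusted p = 0.0457) and CCoAMT (F = 9.27, adjusted p = 0.0477), each below 0 in A and above 0 in B. By limma 181 of 7591 clones differed, 8 of them with a product. A and B had opposite signs in 63.0% of all clones tested and in 176 of the 181, which were selected for a difference between lines, and C lay between them in 154. All 8 named calls were lost without B control plant 1 (adjusted p from 0.0836 to 0.185) and without A drought plant 1 (0.0573 to 0.227), 7 without B drought plant 1 or 2, 6 without A control plant 1, 5 without A control plant 2, 3 without B control plant 2, 2 without A drought plant 2 and 1 without C drought plant 2 (CCoAMT, 0.0546). The count of clones was 14 without B control plant 1, 24 without A drought plant 1, 25 without B drought plant 2, 27 without A control plant 1, 40 without B drought plant 1, 92 without A control plant 2, 96 without B control plant 2, 18 with tubers fitted apart from leaves and 0 with only arrays that share no plant, and none of the 8 genes passed in the last 2 (adjusted p from 0.0528 to 0.124 and from 0.0583 to 0.353). CDPK2 and CCoAMT were also lost with complete clones only (0.0523 and 0.0571), dnaJ and CDPK2 with scaled arrays (0.0623 and 0.0919) and CCoAMT with centred arrays (0.0513). With the B tuber set turned, an alternative chosen after the data were seen, 3 clones and none of the 8 genes passed (0.0840 to 0.944).

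**Figure D2:**
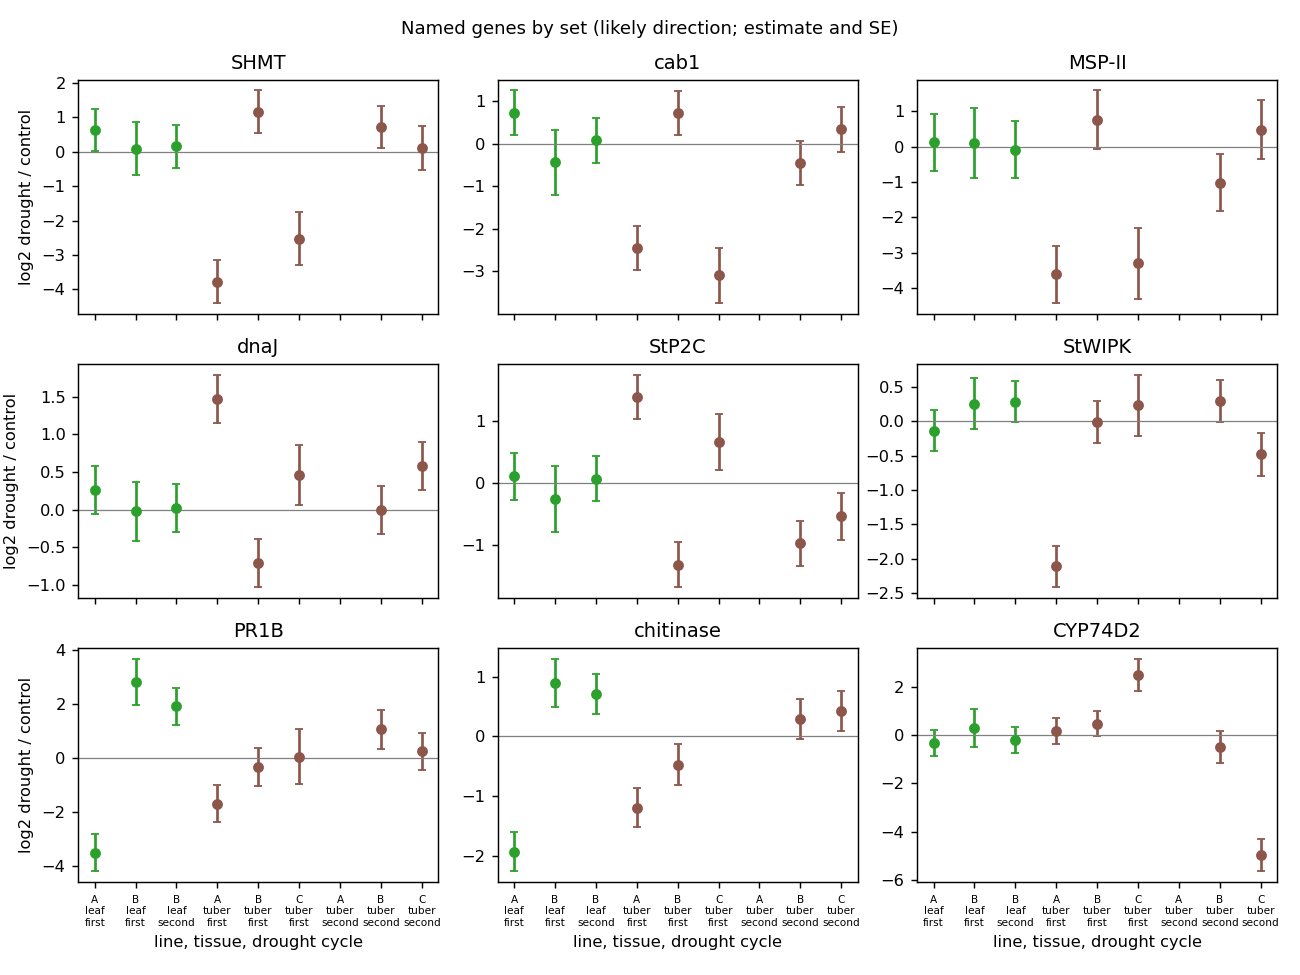
Drought-control log2 ratio (y axis, points) with its standard error (bars) of 9 named genes in each set (x axis). SHMT and cab1 lie below 0 in first-cycle tubers of A and C and above 0 in those of B, and PR1B lies at −3.52 in leaves of A and at 2.83 in those of B.

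Leaves of line A had less transcript of 2 defence genes after the first drought. PR1B, pathogenesis-related protein 1b, fell by 3.52 on the log2 scale (SE 0.695, adjusted p = 0.0292), and a chitinase (LOC102590998), which cleaves fungal cell wall chitin, had a log2 change of −1.94 ± 0.329 (adjusted p = 0.00995), each lower on 4 of 4 arrays of 2 drought and 2 control plants. Of 6 clones in the list of pathogenesis-related proteins, 5 were below 0, 2 fell over all clones and 4 adjusted over the list alone. The exception was the antimicrobial peptide gene sn1 (0.17), and the median was −1.96 (adjusted p = 1.33e-07, and adjusted p = 0.469 with an estimated correlation). The sterol list, here the solanidine glycosyltransferase SGA and the sterol reductases StSSR1 and StSSR2, was low as well. All 6 of its clones were below 0, with a median of −1.93, and 4 passed adjusted over the list alone but 0 over all clones (adjusted p = 1.46e-05, and adjusted p = 0.491 with an estimated correlation). By limma 26 of 10818 clones passed, 5 higher and 21 lower, and 21 of the 26 have no gene. The count was 4 without control plant 1, 8 without control plant 2 and 6 without drought plant 1. Without these plants neither PR1B (adjusted p = 0.150, 0.308 and 0.479) nor the chitinase (0.137, 0.145 and 0.270) passed, and they stood at 0.214 and 0.171 with leaves fitted apart from tubers and at 0.197 and 0.293 with only arrays that share no plant.

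Leaves of line B, from 1 drought plant and 2 control plants, had these defence genes on the other side of 0. PR1B was at 2.83 ± 0.850 and higher in drought on 3 of 3 arrays, though its adjusted p was 1.0. The list median was 1.13, with 5 of 6 clones above 0 and 1 past the threshold adjusted over the list alone (adjusted p = 0.000732, and adjusted p = 0.914 with an estimated correlation). The list of jasmonate synthesis, 5 lipoxygenase clones that were all below 0, had a median of −0.85 (adjusted p = 0.0450, and adjusted p = 0.914 with an estimated correlation). After PR1B, the smallest p values were those of PGAM, the glycolytic phosphoglycerate mutase (0.84), and FeS1, the mitochondrial Rieske protein (0.83). In B, 0 of 10661 clones passed by limma, with 320 at an unadjusted p under 0.05, fewer than the 1 in 20 of chance.

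The difference between the lines in leaf was tested for the same genes. The response in A minus that in B was −6.35 ± 1.10 for PR1B (adjusted p = 0.0227) and −2.84 ± 0.520 for the chitinase (adjusted p = 0.0346). The response in B rests on 1 drought plant, whose spread was taken to be that of the other sets. By limma 11 of 10632 clones differed, all lower in A, and 9 of the 11 have no gene. Both genes were lost without A control plant 1 (adjusted p = 0.0611 and 0.117), A control plant 2 (0.182 and 0.246), A drought plant 1 (0.201 and 0.359) or B control plant 1 (0.199 and 0.205), and also with leaves fitted apart (0.396 and 0.450) or with only arrays that share no plant (0.120 and 0.285). The count without those 4 plants was 0, 0, 2 and 1, 20 without B control plant 2, 0 with leaves fitted apart, 0 with only arrays that share no plant and 1 with arrays blocked on plant number.

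Averaged over A and B after the first drought, all 6 clones of the sterol list were below 0 in leaf. With 1 value per gene 0 lists passed. The median of the sterol clones was −1.0 (adjusted p = 0.00230, and adjusted p = 0.572 with an estimated correlation), and 0 of them passed even adjusted over the list alone. The named genes with the smallest p were R1, the glucan water dikinase of starch breakdown (0.60 ± 0.194, adjusted p = 0.739), PME1, a pectin methylesterase of the cell wall (−1.41 ± 0.426, adjusted p = 0.752), and agpS2, of starch synthesis (0.49, adjusted p = 0.808). R1 was above 0 and PME1 below 0 on all 7 leaf arrays of the first cycle. In this mean 0 of 10632 clones passed by limma, with 515 at an unadjusted p under 0.05, fewer than 1 in 20. The count was 1 without A drought plant 1 or A drought plant 2 and 8 without B control plant 1.

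After the second drought, measured in leaves of B alone, most clones of the defence list were again above 0. Across all clones, the pairs of arrays that share no plant correlated at r = −0.104 and −0.519. PR1B was at 1.91 ± 0.695 and higher on 4 of 4 arrays, but did not pass (adjusted p = 1.0). The list of pathogenesis-related proteins had 5 of 6 clones above 0 and a median of 0.79 (adjusted p = 0.00216, and adjusted p = 0.578 with an estimated correlation). The sterol list had all 6 clones below 0 and a median of −1.14 (adjusted p = 0.00216, and adjusted p = 0.578 with an estimated correlation). All 8 dnaJ clones and all 3 clones of the ribosomal protein RPL27 were above 0, with list medians of 0.31 (adjusted p = 0.0305) and 0.50 (adjusted p = 0.0206), both at adjusted p = 0.578 with an estimated correlation. F3H, the flavanone hydroxylase of flavonoid synthesis, was at 1.67 ± 0.610 and cy-F1, the cytosolic fructose bisphosphatase of sucrose synthesis, at 0.98, neither past the threshold. By limma 1 of 10681 clones passed, spot 151274 without a gene name, chosen after its value was seen (−2.08 ± 0.333, adjusted p = 0.0223, lower on 4 of 4 arrays). The count was 0 without control plant 1 or drought plant 1, 5 without drought plant 2 and 10 without control plant 2.

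The second response in B leaves minus the first was also tested. StWHY2, a Whirly transcription factor, was at −1.37, PGAM at −1.05 and KST1, a guard-cell potassium channel, at −0.93, each at an adjusted p of 1.0. StWHY2 was above 0 on 3 of 3 arrays of the first cycle and below 0 on 4 of 4 of the second. Between the cycles 0 of 10538 clones passed by limma, with 273 at an unadjusted p under 0.05, fewer than 1 in 20, and 1 without control plant 1 of the first cycle.

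In tubers after the second drought, CYP74D2 was low in line C. The divinyl ether synthase transcript fell by 4.98 on the log2 scale there (SE 0.659, adjusted p = 0.00457), with a value on 2 of the 4 arrays, both below 0. Both arrays share drought plant 1, so the call rests on 1 drought plant. It passed without control plant 1 (adjusted p = 0.0144) or control plant 2 (0.00759). It did not pass with tubers fitted apart from leaves (0.0947), arrays scaled to 1 spread (0.182), array quality weights (0.0572) or only arrays that share no plant (0.297). The proteins of tuber storage and protease inhibition pointed both ways in C, with array medians from −5.03 to 3.47. The polyamine list had 8 of 9 clones below 0 and a median of −0.58 (adjusted p = 0.0214, and adjusted p = 0.860 with an estimated correlation). By limma 3 of 10108 clones passed in C. Besides CYP74D2 they were spots 132812 (−3.60 ± 0.466) and 158622 (−2.77 ± 0.360), chosen after their values were seen. The count was 14 without drought plant 1, 38 without control plant 1, 56 without control plant 2 and 226 without drought plant 2, and 1 without the array of control plant 1 and drought plant 1, left out after the data were seen.

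In tubers of B the second drought gave high values of F3H (3.23 ± 0.610, adjusted p = 0.207) and of the vacuolar processing enzyme VPE2 (2.90, adjusted p = 1.0), each above 0 on 4 of 4 arrays. StP2C was at −0.97 and below 0 on 4 of 4 arrays. The photosystem list had 13 of 14 clones below 0 and a median of −0.83 (adjusted p = 0.00367, and adjusted p = 0.712 with an estimated correlation). Its array medians were −0.34, −2.73, 0.985 and −0.94. On its 10 complete clones, the drought plants differed by a median of 1.95 and the control plants by 1.56, against −0.47 between drought and control. The 4 clones of PIN-II, a wound-induced protease inhibitor, were all below 0 in B, with a median of −1.67. By limma 0 of 10712 clones passed, with 372 at an unadjusted p under 0.05, fewer than 1 in 20. The count was 2 without drought plant 1 or 2, 3 without control plant 1 and 30 without control plant 2, and F3H passed without control plant 2 (adjusted p = 0.0469) or drought plant 2 (0.0498).

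Averaged over B and C after the second drought, most clones of the polyamine and sterol lists were below 0 in tuber. These are repeat clones of few genes, and with 1 value per gene 0 lists passed. The polyamine list had too few genes for that test. The polyamine list, AdoMetDC and the spermidine synthase SpdSy, had 8 of 9 clones below 0 and a median of −0.36 (adjusted p = 0.00138), and the sterol list 5 of 6 and a median of −0.89 (adjusted p = 0.0278). Both were at adjusted p = 0.757 with an estimated correlation. CYP74D2 was at −2.75 ± 0.466 (adjusted p = 0.0628), HPL, the hydroperoxide lyase of green leaf volatiles, at −1.18 ± 0.279 (adjusted p = 0.246) and AAC at −0.55 ± 0.144 (adjusted p = 0.291). HPL was below 0 on all 6 arrays that measured it and AAC on all 8. By limma 0 of 10017 clones passed, with 648 at an unadjusted p under 0.05. The count was 1 without B drought plant 2, 4 without C drought plant 1, 5 without B control plant 1, 6 without C control plant 1, 55 without C control plant 2 and 176 without C drought plant 2, and it was 405 with A, which has 1 array, added as a line. CYP74D2 passed without B control plant 1 (adjusted p = 0.0288), B drought plant 2 (0.0101), C control plant 2 (0.0230) or C drought plant 2 (0.00624), though B control plant 1 and C drought plant 2 have no value of it. Leaving out C drought plant 2 also brought HPL (0.0290) and AAC (0.0360) past the threshold.

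The responses of B and C tubers to the second drought were set against each other. The response in B minus that in C was 4.48 ± 0.932 for CYP74D2 (adjusted p = 0.333), 4.09 ± 0.974 for F3H (adjusted p = 0.468) and 1.24 for FLS, the flavonol synthase (adjusted p = 0.958). F3H was above 0 on 4 of 4 arrays of B and below 0 on both C arrays that measured it. By limma 0 of 10017 clones passed, with 434 at an unadjusted p under 0.05, fewer than 1 in 20. The count was 24 without B control plant 2, 1 without C control plant 1, 10 without C control plant 2, 4 without C drought plant 1 and 17 without C drought plant 2.

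CYP74D2 also passed the threshold between the cycles in tuber. Over B and C, its second response minus its first was −4.23 ± 0.629 (adjusted p = 0.0174), from 2.50 in the first cycle to −4.98 in the second in C, and from 0.47 to −0.51 in B. The mean thus rested mainly on C, with 1 control plant in the first cycle and 1 drought plant with a value in the second. By limma 2 of 7566 clones passed, CYP74D2 and spot 145150, which has no gene name and was chosen after its value was seen (−1.66 ± 0.276, adjusted p = 0.0297). Control plants 1 and 2 and drought plant 1 of the first cycle of B each ended the CYP74D2 call (adjusted p = 0.0598, 0.0862 and 0.0905), with 0 clones called without any 1 of them, it had no value without B control plant 2 or C drought plant 1 of the second cycle, and it stood at 0.0888 with arrays scaled to 1 spread, at 0.297 with tubers fitted apart, at 0.667 with only arrays that share no plant and at 0.0768 with the B tuber set of the first cycle turned. The count was 6 without B drought plant 2 and 1 without C drought plant 1 of the first cycle, and in the second cycle 0 without B control plant 2, 1 without B control plant 1, B drought plant 1, B drought plant 2 or C drought plant 1, 7 without C control plant 2 and 30 without C drought plant 2.

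Leaves and tubers of the same line and cycle were compared in 3 pairs of sets, A and B in the first cycle and B in the second. The photosystem genes stood apart by list, higher in the leaf response than in the tuber response in all 13 measured clones on the mean of the 3 pairs. In A the list medians were 0.54 in leaf and −2.76 in tuber, and in B after the second drought −0.07 and −0.83, but in B after the first drought the order was reversed, at 0.04 and 0.74. The median difference was 1.09 (adjusted p = 6.19e-08), a p that rests on the preset correlation, since neither an estimated correlation nor fry could be computed for this list. Starch and sucrose genes had 18 of 24 clones above 0 and a median of 0.18 (adjusted p = 0.00335), and polyamine genes 8 of 9 and 0.27 (adjusted p = 0.00796), both at adjusted p = 0.341 with an estimated correlation. All 6 sterol clones were below 0, with a median of −1.06 (adjusted p = 0.00206, and adjusted p = 0.568 with an estimated correlation). PSBR was at 1.09, StWIPK at 0.74 and R1 at 0.60, each at an adjusted p of 1.0. Between leaf and tuber 0 of 10138 clones passed by limma, with 250 at an unadjusted p under 0.05, fewer than 1 in 20. Leaf and tuber were fitted as independent, so this test may be too strict if they came from the same plants.

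Across clones, which are not independent replicates, the responses of the 9 sets had little in common. Pearson's r had a median of 0.0501 over the 36 pairs of sets. Between leaf and tuber of the same line and cycle it was 0.205 in A after the first drought, 0.118 in B after the first and 0.164 in B after the second. Tubers of A and B ran against each other in the first cycle (r = −0.391), while those of A and C ran together (r = 0.466), and in the second cycle the 1 array of A ran with C (r = 0.567). Within a set, arrays that shared a plant had a median r of 0.509 over 26 pairs, arrays that shared no plant 0.166 over 12 pairs and arrays of different sets 0.0117 over 368 pairs.

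**Figure D3:**
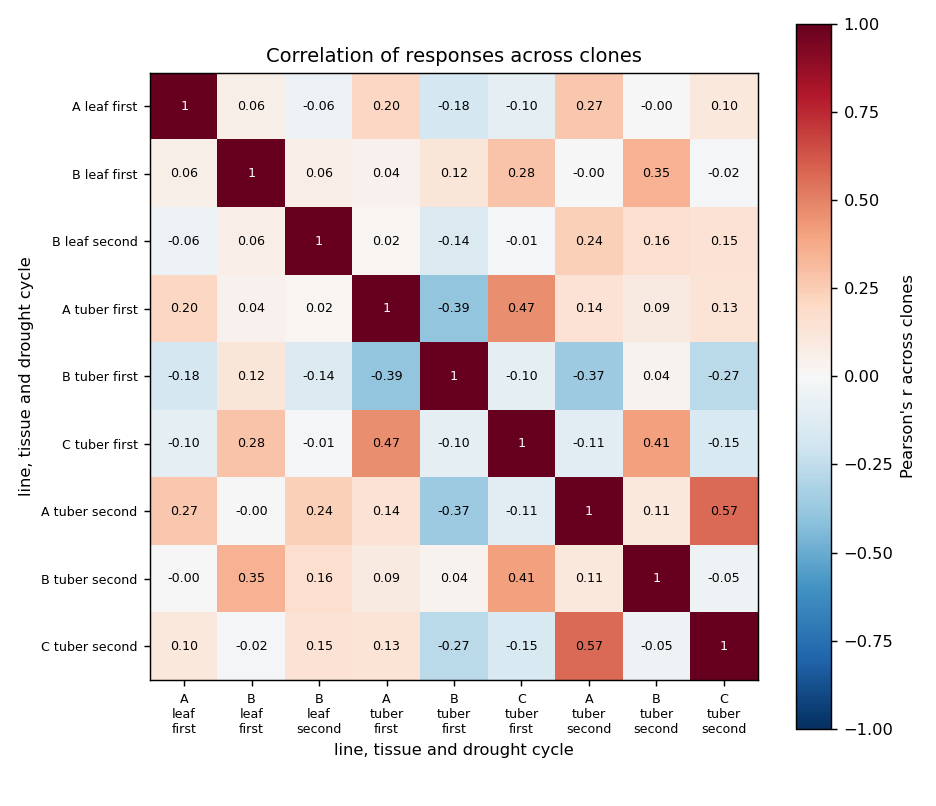
Pearson's r across clones between the drought responses of each pair of sets (both axes, cells coloured and labelled by r). The lowest value is −0.391 between first-cycle tubers of A and B, and the highest 0.567 between second-cycle tubers of A and C.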

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

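The splits of plants or arrays, the leaving out of single plants and the count with arrays taken as independent were planned, while the tests of plant differences within a treatment, of a response shared by the 3 lines and of exchanged B tubers were chosen after the result was seen.

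The tuber response to the first drought was flagged because it differed between the lines by a direct test, in 181 clones. The named genes flagged with it were SHMT (F = 16.7), StWIPK (F = 15.6), StP2C (F = 14.7), LPD2 (F = 14.3), cab1 (F = 13.8), dnaJ (F = 11.8), CDPK2 (F = 9.45) and CCoAMT (F = 9.27). In 1 of 100 splits of the arrays between lines, the real one, were as many clones called, with 112 as the highest of the others. The arrays of a line share plants, which these splits part, so the real grouping can stand out through shared plants alone and chance among plants is not excluded. The count was 0 with only arrays that share no plant and 18 with tubers fitted apart from leaves. It was 14 without B control plant 1, 24 without A drought plant 1, 25 without B drought plant 2, 27 without A control plant 1, 40 without B drought plant 1, 92 without A control plant 2 and 96 without B control plant 2, and all 8 genes lost the threshold without B control plant 1 or A drought plant 1, or with the B tuber set turned, which left 3 clones and was chosen after the data were seen.

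The fall of the photosystem genes in first-cycle tubers of A, against their higher values in B, was weighed against 3 explanations. That 1 plant alone carried the fall in A was argued against, since without any 1 plant the list median was −2.03 or further from 0, though without drought plant 1 the 4 photosystem genes no longer passed. Differences between plants of the same treatment cannot be told apart from a drought response, with medians of −1.50 between the drought plants of A, 0.509 of the drought-control difference, and of −1.38 between the control plants of B, where only 5 of 14 clones, with a drought-control median of 0.30, gave it. A drought response shared by the 3 lines cannot be told apart from a line difference, since the median in B was −0.89 without its control plant 1, a value that rests on 1 array for most clones (13 clones on that array and 5 on the other). Line, as the design names it, stays open as a biological explanation, as does a difference in green tissue between tubers, which was not tested.

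The mean tuber response to the first drought called 3 clones. As many were called in 11 of 100 splits of the plants within sets, so chance cannot be excluded. The highest other split called 320 and equals the labels of B exchanged, which points to a structure of these samples. An exchange of control and drought in the B tuber set cannot be told apart from a line difference, since leaf and tuber of B correlated at r = 0.118 in that cycle, where leaf and tuber sets of different lines reached 0.283 in size.

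The leaf response to the first drought was flagged for a difference between A and B in 11 clones, with −6.35 for PR1B and −2.84 for the chitinase, where the response in B rests on 1 drought plant. With 15 splits of the arrays, too few for a share under 0.05, the highest other split called 3. Both genes lost the threshold without A control plant 1, A control plant 2, A drought plant 1 or B control plant 1, with 0, 0, 2 and 1 clones called, and 20 were called without B control plant 2.

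The tuber response was flagged for a difference between the cycles in 2 clones, with −4.23 for CYP74D2. The gene lost the threshold without control plant 1, control plant 2 or drought plant 1 of the first cycle of B (adjusted p = 0.0598, 0.0862 and 0.0905), and up to 30 clones were called without C drought plant 2 of the second. As many were called in 70 of 100 splits of the arrays between cycles, with 208 as the highest other, so chance cannot be excluded, and such a count points to a structure of the samples.

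The array of control plant 2 and drought plant 2 in the second-cycle tubers of B was flagged as far from the other 3 of its set, with a correlation of 0.893 between duplicate spots. Chance flags about 1 group in 20, and this was 1 flag in 48 groups.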

How the results depend on the processing

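In the comparisons that have a sign, no named gene past the threshold changed sign under any alternative. The turned reading of the ratio changes every sign. The F-test for the lines has no sign, though its B values change theirs with the B tuber set turned. Values that had not passed changed sign in first-cycle tubers of B. With that set turned, StP2C went to 1.31, AAC to −0.72, LPD2 to −0.80 and the photosystem median to −0.74, and without control plant 1 the photosystem median went to −0.89. Of 370 alternative results, most of them counts, 191 were labelled the same and 179 moved. A count was the same within 1.5 times the reported count, and a leaf-tuber correlation within the standard deviation of its pairs. Correlations of the dye-exchanged pair were set to the same without a rule. For single named genes and the photosystem medians 742 values kept their sign and, for genes, their call, 176 lost and 54 gained the threshold, and the 5 above moved. The F-tests among them were judged by their call alone. Where no reason is given, the cause was not tested. Robust moderation and leaving out the dye-exchanged array left each count within 1.5 times, and centring moved set medians by at most 0.033. Spots without a value limit the tests of complete clones, and signal over background is not given in the sources used here.

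With arrays taken as independent, which counts a shared plant several times, the calls were 448 for the mean leaf response to the first drought, 59 for B leaves in the second, 656 for the mean tuber response to the first, 501 to the second, 50 for leaf against tuber, 73 for the cycles in leaf, 363 for the cycles in tuber, 2138 for lines in first-cycle tubers, 171 in second-cycle tubers and 257 in leaf. For single sets they were 812 in A leaves, 170 in B leaves, 2671 in A tubers, 919 in B tubers and 96 in C tubers of the first cycle, and 135 in B tubers and 744 in C tubers of the second.

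With only arrays that share no plant (fewer arrays), the calls were 0 for B leaves in the second cycle, 1 for the mean first tuber response, 0 for the cycles in tuber, 0 for lines in first-cycle tubers, 0 for lines in leaf, 4 for A leaves, 41 for A tubers, 0 for first-cycle and 0 for second-cycle C tubers, and the median leaf-tuber r was 0.243. With the tissues fitted apart (fewer arrays behind the spread), they were 0, 0, 0, 18, 0, 9, 234, 1 and 0 in the same order. With complete clones only (fewer clones), they were 0 for the mean first tuber response, 1 for the second, 0 for the cycles in tuber, 90 for lines in first-cycle tubers, 1 for lines in leaf, 4 for A leaves, 237 for A tubers, and 0 and 0 for C tubers.

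Arrays scaled to 1 spread gave 2 for the mean first leaf response, 3 for the second, 1 for the cycles in leaf, 1 for the cycles in tuber, 80 for lines in first-cycle tubers, 1 in second-cycle tubers, 17 in leaf, 56 for A leaves, 1 for B leaves, 28 for A tubers, 9 for B tubers, 1 for second-cycle B tubers and 0 for C tubers. Centred arrays gave 5 for the mean first tuber response. Array weights gave 214 for it, 3 for the second, 6 for the cycles in tuber, 1105 for lines in first-cycle tubers, 18 for lines in leaf, 174 for A leaves, 1324 for A tubers, 311 for B tubers, 15 for first-cycle and 0 for second-cycle C tubers, and a median leaf-tuber r of 0.106.

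Each spot tested alone, chosen after the data were seen, gave 2 for B leaves in the second cycle, 9 for the mean first tuber response, 326 for lines in first-cycle tubers, 47 for A leaves, 939 for A tubers, 1 for first-cycle and 2 for second-cycle B tubers. Turning the B tuber set, also chosen later, gave 320 for the mean first tuber response, 1 for leaf against tuber, 0 for the cycles in tuber and 3 for lines. Leaving out the C array of control plant 1 and drought plant 1, also chosen later, gave 1 for second-cycle C tubers. With A added as a line, the mean second tuber response called 405. A log2 change of at least 1 beside the threshold left 381 in A tubers.

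Blocking on plant number gave 5 for the cycles in tuber and 1 for lines in leaf. Plant differences within a treatment correlated above 0 between leaf and tuber of the same numbers, at 0.0933 to 0.613. Whether the numbers pair plants stays open. With an estimated correlation and with fry, 0 lists passed in the comparisons of the report except 1 by fry in second-cycle B tubers. For single sets both had few residual degrees of freedom, so these losses do not show that a list is unchanged. Lists with fewer than 3 genes could not be tested with 1 value per gene. With 1 value per gene, 0 passed for the mean first leaf response, 0 for the second, 1 for the mean first tuber response, 0 for the second, 2 for leaf against tuber, 2 for A leaves, 1 for B leaves of the first cycle, 1 for A tubers, 0 for B tubers of either cycle, 1 for first-cycle and 0 for second-cycle C tubers.

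Without 1 plant in turn, calls ran from 0 to 8 for the mean first leaf response, 0 to 10 for the second, 0 to 101 for the mean first tuber response, 0 to 176 for the second, 0 to 0 for leaf against tuber, 0 to 1 for the cycles in leaf, 0 to 30 in tuber, 14 to 252 for lines in first-cycle tubers, 0 to 24 in second-cycle tubers and 0 to 20 in leaf. For single sets they ran from 4 to 26 in A leaves, 0 to 0 in B leaves, 11 to 555 in A tubers, 0 to 6 in B tubers, 5 to 7 in C tubers of the first cycle, and 2 to 30 in B tubers and 14 to 226 in C tubers of the second. The median leaf-tuber r ran from 0.117 to 0.205. Leaving out a plant that all arrays of a set share gave no value, and a set left with 1 plant in an arm was taken to vary like the others.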

Other observations

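The test of the storage protein pattern was chosen after the result was seen, and the splits and the count with arrays as independent were planned.

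Storage protein and protease inhibitor genes, which tubers express at high levels, moved both ways on the arrays of second-cycle C tubers. The list median was −5.03 on the array of control plant 1 and drought plant 1 (6 of 15 clones), and 3.47 on that of control plant 2 and drought plant 2 (9 clones), which shares no plant with it. The other C arrays were at −1.67 (13 clones) and −0.73 (4 clones), so the medians compare different clones, 3 of 4 lay below 0, and the 2 arrays at the extremes had the lowest quality weights of all (0.315 and 0.283). A drought response shared by the C plants cannot be told apart from plant differences, since the value of 3.47 lies within the difference between plants of 1 treatment (−4.38 between the drought plants and 4.08 between the control plants, 2 clones). In B tubers only the 4 clones of the protease inhibitor PIN-II had a value, with medians from −1.87 to −1.35 on the 4 arrays, and for this 1 gene fry gave an adjusted p of 0.0219, against 0.138 by cameraPR.

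The single array of A tubers in the second cycle entered the correlations between sets, but no reported test of clones. It served as a line only in an alternative for the mean second tuber response. This array gave −8.36 for API, an aspartic protease inhibitor, −5.11 for the sterol reductase StSSR2, −4.50 for CYP74D2 and 6.64 for VPE2. The VPE2 value is the lowest deposited one, −6.643, with its sign turned, and so only a bound. Its storage protein median was −4.10, and it correlated at r = 0.772 across clones with the C array of control plant 1 and drought plant 1. The latter ran at r = −0.557 against the C array of control plant 2 and drought plant 2. Of 368 pairs of arrays from different sets, 35 had r below −0.3.

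Patatin, the tuber storage protein, was set down as a marker of tuber tissue in leaf samples. In leaves of A its array medians ran from −0.30 to 0.40, in leaves of B from 0.08 to 1.32 in the first cycle and from −1.12 to 0.29 in the second.

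With arrays taken as independent the mean first tuber response called 656 clones, and another split of the same plants called 1630. That split exchanges the labels of B and keeps those of A and C, so it still holds their responses and decides nothing. In the simulated data 58.0% of calls for this comparison were false with arrays taken as independent, against 3.80% with the shared-plant correlation. How far plants counted several times raise the count in the real data stays open.

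Of the other comparisons, the mean second tuber response called 0 clones with 648 at an unadjusted p under 0.05 by limma, and the 18 splits of the plants within sets are too few for a share under 0.05. The highest other split called 743, and set control plant 2 and drought plant 2 of B with control plant 1 and drought plant 2 of C against the rest, which points to a structure of the plants. For the mean first leaf response, with 0 called and 515 unadjusted, the 18 splits are also too few, with 66 as the highest. For the cycles in leaf, with 0 called and 273 unadjusted, 15 splits are too few, with 6 as the highest. For leaf against tuber, with 0 called and 250 unadjusted, the highest of 100 splits called 1, and for lines in second-cycle tubers, with 0 called and 434 unadjusted, the highest of 35 called 220. Any split calls at least 0 clones, so these counts say nothing about chance.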
